A study of Mus musculus with 12 samples.

How the data were processed

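The 12 samples were thymic T cells of C57BL/6J mice aged 8 to 12 weeks, 50% male and 50% female per the labels, sorted as cells positive for both CD4 and CD8, with or without CD71. Sample titles give a low forward scatter gate for both subsets. Per the labels' protocols, total RNA was extracted with Trizol and a column kit with DNase treatment, checked on a Bioanalyser, and 80 ng was amplified and biotin-labelled with MessageAmp II for 1-colour arrays. The mutant group carries the I15N change in Ncaph2.

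The deposited non-normalized table gives a linear signal intensity and a detection p-value for each of 18138 gene symbols on each array, per the file headers. It has 1 entry per symbol and no probe identifiers, so how several probes of a gene were combined, if they were, is not given in the sources used here. The authors' processed intensity values form a second deposited table of 18132 symbols, for which the submitters' processing notes name RMA. Its columns rank genes as the non-normalized signal does (rank correlation 1), have medians of 77.2 to 78.7 and run from 75.7 to 12817. The scale is therefore linear, genes were not centred and the direction is that of the signal. The background step stays unknown. The deposited detection p-value is not a strict function of signal, since 2 of the 1145 genes that rank among the brightest 10% on all arrays are detected on none. Columns were matched to samples by their names. No 2 arrays held identical values, and 0 columns of other samples were present.

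Signals were background corrected and normalized with neqc in limma 3.58.1 (R 4.3.3), which infers the mean and spread of the background from the detection p-values, adds an offset of 16, quantile-normalizes the arrays and takes log2. The inferred background mean was 75.7 to 107 per array, against a median signal of 71.5 to 95.9 for genes with a detection p over 0.5, so the background may be set somewhat high. The offset understates the change of dim genes. Genes with a detection p under 0.05 on at least 3 arrays were tested, 8247 in all. The fixed plan spoke of probes, and symbols took their place. Mean signal differed 2.13-fold between the brightest and the dimmest array.

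One linear model with 4 group means was fitted to all 12 arrays with lmFit and eBayes without trend, so the groups share an estimate of the spread. The contrasts were mutant against wild type in each subset, their average, their difference, and CD71-positive against CD71-negative cells in each genotype. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg within a contrast, and an adjusted p under 0.05 counted as past the threshold. Values are log2 differences with the standard error of the fit and 3 arrays per group. A gene that no array of a group detected has only a bound there, given as at least so many fold. It sets the brighter group's mean against the mean of, per array, the higher of the lowest detected signal and the gene's own.

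The 24 gene lists held 490 genes, of which 432 were on the array and 311 were tested. They cover condensin, cell cycle phases, histones, p53, DNA repair, interferon, metabolism, stages and signals of thymocytes, apoptosis, leukaemia, stress, ribosomes, sex-linked genes and markers of other cell types of the thymus. Lists with at least 3 tested genes were tested by camera with a preset correlation of 0.01, adjusted within a contrast over 23 lists. The erythroid list had 1 tested gene and was not tested. Calls with the preset correlation do not allow for the correlation measured among a list's genes, so the adjusted p with an estimated correlation is given beside each, and fry was run as well. Where current symbols differ they stand in parentheses, from RefSeq annotation of GRCm38.p6, which matched 14309 symbols directly and 2886 as synonyms and left 943 unmatched. The same table gave the genes within 20 Mb of Ncaph2.

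The design, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes Ncaph2, Tfrc, Cd4, Cd8a and Cd8b1, the 10 largest rises and 10 largest falls past the threshold whose arrays did not overlap and whose symbol has a match, the 5 smallest p-values in each direction where fewer than 5 pass, and up to 4 members of each list by p-value. Between mutant subsets it takes the genes named in wild type. Cd8a was detected on 0 arrays and has no value. List members past the test over the list alone are named beyond the rule in places, and some genes that the rule takes are not reported here.

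The fit was tested on simulated data with 200 of 8247 genes changed in each of 10 runs, beside a list of 20 genes raised by 0.5. Noise was drawn independently for each gene and array around normalized group means. Background correction, normalization and correlation between genes were not simulated, so the rates hold for independent noise only. At a log2 change of 0.5 the fit recovered 69.0%, 68.8% and 79.7% of the changed genes in CD71-negative cells, CD71-positive cells and the average. At a change of 1 it recovered 88.7%, 88.4% and 96.3%. Of the calls, 5.39%, 5.98% and 5.27% were genes not changed. Alternatives covered cyclic loess, no background correction, normexp with an offset of 50, the authors' values, 2 other filters, a trended robust fit, array weights, only the arrays compared, the replicate number as a block and leaving out each array. A brightness covariate and a background from dim genes were added after the data were seen.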

Results

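RNA was measured in thymic T cells sorted by flow cytometry from wild-type mice and from mice carrying the I15N missense change in Ncaph2, the kleisin subunit of condensin II, a ring-shaped complex that compacts chromosomes for cell division. The labels write the gene as Caph2. All sorted cells carried both CD4 and CD8, as most immature thymocytes do, and were divided by CD71, the transferrin receptor, which proliferating cells display. The 4 groups were wild-type CD71-negative, wild-type CD71-positive, mutant CD71-negative and mutant CD71-positive cells, with 3 arrays in each. The labels do not say whether the 3 samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Mean signal per array lay between 95.1 and 203, and 5893 to 7415 of 18138 genes were detected on an array. Arrays of the same group correlated at 0.963 to 0.993 across genes and arrays of different groups at 0.843 to 0.991. The first principal component carried 71.9% of the variance and separated CD71-positive from CD71-negative arrays. Within groups, the brightness of an array went with the leading component of its deviations from the group mean (12 arrays, Pearson r = 0.82, permutation p = 0.0016, Spearman rho = 0.90, permutation p = 0.00012), and r was 0.78 without the 2 arrays farthest from the median brightness. The number of arrays limits the precision of every value below.

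Ncaph2, the mutated gene, was detected on all 12 arrays, and its RNA level was close between genotypes in both subsets. Its normalized log2 signal averaged 6.53 ± 0.27 in wild-type and 6.42 ± 0.14 in mutant CD71-negative cells, and 7.76 ± 0.22 and 7.72 ± 0.18 in CD71-positive cells (SD, n = 3). The genotype difference was -0.11 ± 0.16 (SE) in CD71-negative cells (adjusted p = 0.90) and -0.04 ± 0.16 in CD71-positive cells (adjusted p = 1.0). A missense change need not alter the RNA level, so these values do not check the genotype labels. Ncaph2 was higher in CD71-positive than in CD71-negative cells, by 1.22 ± 0.16 in wild type (adjusted p = 0.00055) and 1.30 ± 0.16 in mutants (adjusted p = 0.00036).

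The first comparison set CD71-positive against CD71-negative cells within wild type and describes the sorted populations. Wild-type CD71-positive cells had far higher RNA levels of cell division genes and lower levels of genes typical of resting double-positive thymocytes. Tfrc, which encodes CD71, was higher by 1.15 ± 0.28 on the log2 scale (2.22-fold, adjusted p = 0.014), while Cd4 and Cd8b1 were lower by -0.79 and -1.13 (adjusted p = 0.0071 and 0.0010). The largest rises belonged to Prc1, which bundles microtubules of the central spindle (4.99 ± 0.17, 31.9-fold), Top2a, the DNA topoisomerase that untangles chromosomes (4.66 ± 0.27), the mitotic kinase gene Pbk (4.45 ± 0.17) and Birc5, a member of the chromosomal passenger complex (4.11 ± 0.22). They were followed by 2810417H13Rik (Pclaf), Kif22, Cenpa, Plk1, Cdca3 and Aurka, between 3.64 and 4.09. The largest falls belonged to Gimap8, a GTPase gene of lymphocytes (-2.93 ± 0.24), the sialyltransferase gene St6gal1 (-2.74 ± 0.29), Wdr78 (-2.66 ± 0.29), the early growth response gene Egr1 (-2.64 ± 0.43) and the meiotic recombination gene Spo11 (-2.59 ± 0.34). Gimap6, Txnip, P2ry5 (Lpar6) and the activation marker gene Cd69 fell by 2.13 to 2.41. Ypel3 was detected on 2 of 3 wild-type CD71-negative arrays and 0 of 3 CD71-positive arrays, where it was at least 5.03-fold lower. By limma, 2067 of 8247 genes passed an adjusted p under 0.05, 987 higher and 1080 lower in CD71-positive cells. The arrays of the 2 groups did not overlap for 2036 of them. Chance gives this separation to 10% of unselected genes, and selection by p-value favours it, so it is no separate evidence.

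Gene lists described the same contrast by process. Of 22 tested genes of mitosis, 19 rose and 0 fell (20 and 0 adjusted over the list alone), with a median log2 difference of 3.00 (camera, adjusted p = 1.0e-22). DNA replication genes had 22 of 27 members higher (24 adjusted over the list alone), among them the helicase subunit gene Mcm5 at 3.33 and the ribonucleotide reductase gene Rrm1 at 3.28, with a median of 1.66 (adjusted p = 1.0e-20). The double-positive thymocyte list had 12 members lower and 1 higher of 19 (15 and 1 adjusted over the list alone), among them Cd2 at -1.84 and the recombinase gene Rag1 at -1.43 (adjusted p = 4.2e-06). These 3 lists also passed with an estimated correlation between genes, at adjusted p = 0.025, 0.029 and 0.029. Condensin subunit genes rose in 5 of 6 cases, led by Ncaph of condensin I at 3.03 and Ncapd2 at 2.03 (5 adjusted over the list alone, camera adjusted p = 1.8e-05, adjusted p = 0.075 with an estimated correlation). Genes of Myc and ribosome biogenesis rose in 10 of 15 cases, with the nucleolar protein gene Nol5 (Nop58) at 1.94 (11 adjusted over the list alone, adjusted p = 2.0e-05, adjusted p = 0.055 with an estimated correlation). Replication-dependent histones rose in 12 of 24 cases (15 adjusted over the list alone, adjusted p = 4.2e-06, adjusted p = 0.23 with an estimated correlation), with Hist1h2ag (H2ac11) at 3.22. DNA repair genes had 10 of 22 higher and 1 lower (11 and 2 adjusted over the list alone, adjusted p = 4.3e-06, adjusted p = 0.075 with an estimated correlation). Genes of positive selection and T-cell receptor signalling had 8 of 13 lower and 0 higher (8 adjusted over the list alone), including Egr1 and the receptor gene Cd6 at -1.33 (adjusted p = 0.0012, adjusted p = 0.12 with an estimated correlation). Ribosomal protein genes (6 higher and 1 lower of 20, 8 and 1 adjusted over the list alone) and cholesterol synthesis genes (4 higher of 12, 4 adjusted over the list alone) passed at adjusted p = 0.031 and 0.048, with adjusted p = 0.51 and 0.12 with an estimated correlation. The ribosomal call was lost without wild-type CD71-negative array 3 or wild-type CD71-positive array 1 (adjusted p = 0.20 and 0.062). The cholesterol call was lost without array 2 or 3 of wild-type CD71-negative, mutant CD71-negative or mutant CD71-positive cells, or array 1 or 3 of wild-type CD71-positive cells (adjusted p = 0.050 to 0.12).

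**Figure D1:**
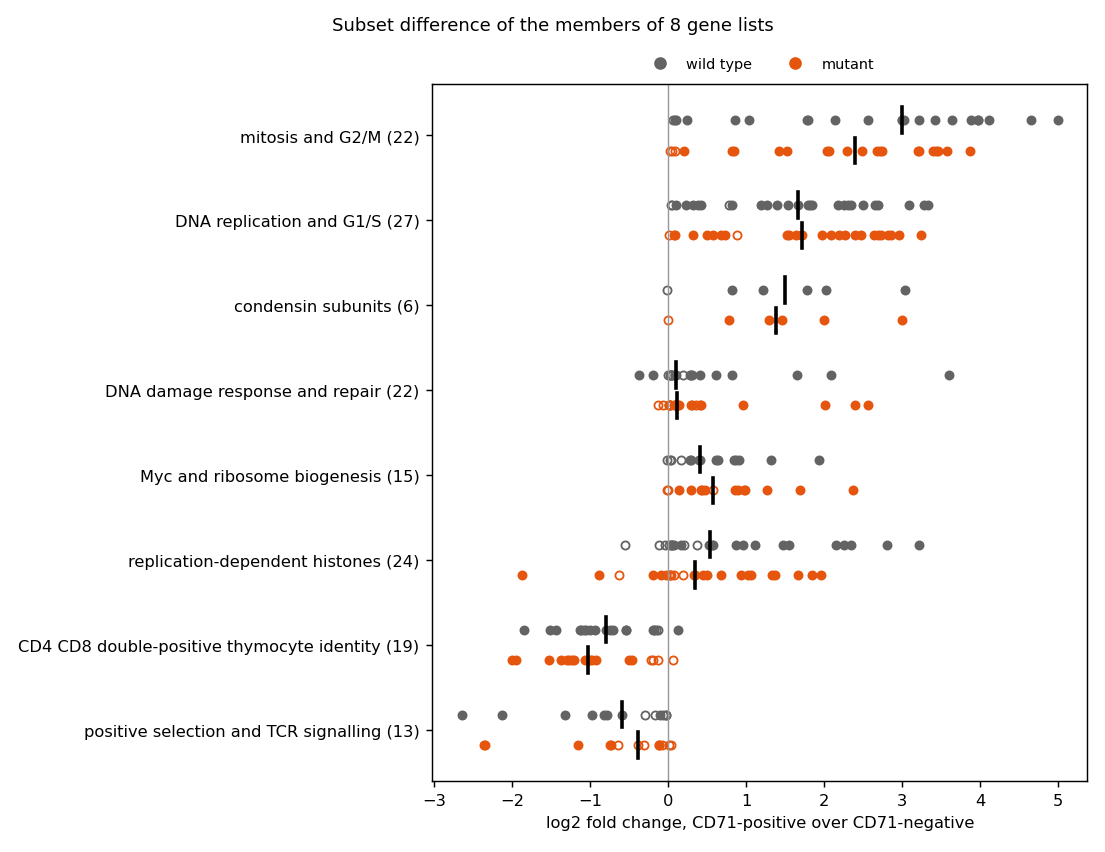
Log2 fold change of CD71-positive over CD71-negative cells (x axis) for each tested member of 8 gene lists (y axis, number of genes in parentheses), in wild type (grey) and mutants (orange). Filled points passed an adjusted p under 0.05 over the list alone and black bars are medians; the mitosis list has a median of 3.00 in wild type and 2.39 in mutants.

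In mutants the same comparison gave 2375 genes, 1193 higher and 1182 lower in CD71-positive cells. Of these genes selected by p-value, 2353 had arrays that did not overlap (10% by chance in unselected genes). Both genotypes called 827 genes higher and 815 lower, with 0 in opposite directions, where independent lists of these sizes would share 143 and 155. The 2 contrasts compare no array in common but share each gene's estimate of spread, so independence understates the overlap to be had by chance. Prc1 was higher by 3.87 ± 0.17 in mutants, Top2a by 3.44 ± 0.27, Pbk by 3.82 ± 0.17 and Birc5 by 3.39 ± 0.22, and Tfrc by 1.30 ± 0.28 (adjusted p = 0.0068). Cd4 and Cd8b1 were lower by -0.93 and -1.29. Of the mitosis list 19 of 22 rose in mutants, with a median of 2.39 (adjusted p = 2.9e-18), and 25 of 27 replication genes rose, with a median of 1.71 (adjusted p = 5.5e-20). The double-positive list had 15 of 19 lower and 0 higher, with Rag1 at -2.00 (adjusted p = 1.7e-07), and the Myc list had 12 of 15 higher (adjusted p = 1.1e-06). All 4 lists had an adjusted p = 0.026 with an estimated correlation. Condensin subunit genes rose in 5 of 6 cases (adjusted p = 4.0e-05, adjusted p = 0.089 with an estimated correlation). DNA repair genes (11 of 22 higher), positive selection genes (6 of 13 lower), histones (11 of 24 higher, 3 lower) and immediate-early genes (5 of 17 lower) passed at adjusted p = 3.2e-06, 0.015, 0.019 and 0.041, with adjusted p = 0.073, 0.23, 0.52 and 0.52 with an estimated correlation. The immediate-early call was lost without wild-type CD71-negative array 1, 2 or 3, mutant CD71-negative array 1 or mutant CD71-positive array 2 or 3 (adjusted p = 0.051 to 0.20). The myeloid and dendritic list, with 3 of 11 members higher (6 adjusted over the list alone), also passed (adjusted p = 0.0043, adjusted p = 0.50 with an estimated correlation). The lysozyme gene Lyz (Lyz1) was 2.00 higher in mutant CD71-positive than in mutant CD71-negative cells, and the antigen-presentation genes Cd74 and H2-Ab1 were 2.35 and 2.26 higher.

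The question named in the series design was how cells of matched surface phenotype differ between genotypes, and it was asked first in CD71-negative cells. The largest rises among genes past the threshold with a matched symbol belonged to 2 entries matched to the interferon-inducible gene Ifi27, Ifi27 at 1.66 and D12Ertd647e at 1.65 ± 0.21 (3.14-fold, adjusted p = 0.016). They were followed by Lgals3bp, which encodes a secreted galectin-binding glycoprotein (1.48 ± 0.20), Usp18, which encodes the protease that removes the interferon-induced modifier Isg15 from proteins (1.45 ± 0.13, adjusted p = 0.0051), and the histone gene Hist1h2an (H2ac22, 1.24 ± 0.16). Tspo, a mitochondrial outer membrane protein gene, the pseudogene 4933439C20Rik (Pisd-ps3), A230050P20Rik (Shfl), an interferon-induced antiviral gene, the selenoprotein gene 2700094K13Rik (Selenoh), the antiviral gene Rsad2 (1.08 ± 0.11, adjusted p = 0.0054) and Hist1h2ah (H2ac12) rose by 1.06 to 1.15. Falls were smaller. They were led by the zinc finger gene Zfp148 (-0.88 ± 0.12), the potassium channel subunit gene Kcnab2 (-0.82 ± 0.12), the RNA uridylyltransferase gene Zcchc6 (Tut7, -0.61 ± 0.08) and the prion protein gene Prnp (-0.57 ± 0.07, adjusted p = 0.011). Zfp282, Gprasp1, Srfbp1, Kcnh3 and Zmym3 fell by 0.31 to 0.53, and Kcnh3 lies within 20 Mb of Ncaph2. Nearby genes were listed for the averaged contrast only, so other genes named here may lie there too. In all 35 genes passed, 23 higher and 12 lower. Each had arrays that did not overlap, which selection by p-value favours (10% by chance in unselected genes). The count was 14 without wild-type array 1, the dimmest of the study, and 123 without wild-type array 3. It was 23 without mutant array 2 and 21 without mutant CD71-positive array 2, which enters through the shared estimate of spread. It was 8 with cyclic loess, 2 when only the CD71-negative arrays were fitted, and 20 with no filter. A trended robust fit, the authors' values, a background from dim genes and array weights gave 53, 55, 59 and 461. The split was 52 higher and 7 lower with the background from dim genes, 53 and 70 without wild-type array 3 and 228 and 233 with array weights.

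Among lists, the interferon response had the smallest p-value in CD71-negative cells. Of its 17 tested genes, 3 rose and 0 fell over all genes tested, and 10 rose and 0 fell adjusted over the list alone (camera, adjusted p = 2.9e-12, adjusted p = 0.080 with an estimated correlation). The median difference was 0.11 and ranged up to 0.53 under other scalings, the latter with the background from dim genes. The members past the test over the list alone ranged from Oasl1 at 0.07 to Ifi27 at 1.66, with Trim30 at 0.97. The file's symbol Ifi27 is also an older name of Ifi27l2a, so this entry may stand for either gene. Replication-dependent histones had 1 of 24 members higher and 0 lower (4 and 0 adjusted over the list alone), with 23 of 24 above 0 and a median of 0.29 (adjusted p = 1.7e-09, adjusted p = 0.21 with an estimated correlation). Hist1h2ag (H2ac11) was 1.44 higher, Hist1h2ad (H2ac7) 1.24, Hist1h3e (H3c6) 1.05 and Hist1h2ao (H2ac23) 0.77. These genes have near-identical copies whose RNA the array could confuse, and Hist1h2ao sits close to the ceiling that quantile normalization sets. Replication and mitosis genes had medians of 0.08 (0.04 to 0.26 under other scalings) and 0.06 (0.0092 to 0.30), against 0.25 to 0.68 for histones, and 0 members called over all genes (adjusted p = 0.0033 and 0.020, adjusted p = 0.45 and 0.47 with an estimated correlation). The centromeric histone gene Cenpa at 1.06 was the 1 mitosis gene past the test over the list alone. The replication call was lost without mutant array 1 (adjusted p = 0.069), and both were lost with cyclic loess (adjusted p = 0.15 and 0.37). Targets of p53 were shifted up (median 0.05), ribosomal protein genes up (0.22), markers of natural killer and innate-like T cells up (0.06), T-cell leukaemia genes down (-0.17, led by Runx1 at -0.32) and positive selection genes down (-0.03), each with 0 calls over all genes. Their adjusted p-values were 0.0094, 0.0094, 0.0099, 0.0094 and 0.047, and adjusted p = 0.10, 0.45, 0.42, 0.10 and 0.45 with an estimated correlation. The calls of these 5 lists and of mitosis were all lost without wild-type CD71-negative array 3, at adjusted p = 0.052 to 0.41. Those of mitosis, ribosomal proteins, leukaemia and positive selection were also lost without mutant array 1, at adjusted p = 0.069 to 0.22. Without wild-type CD71-negative array 2 mitosis, p53 targets and positive selection lost their calls (adjusted p = 0.056, 0.054 and 0.32). The positive selection call was kept without 6 of 12 arrays, and was lost also without wild-type CD71-positive array 2, mutant CD71-negative array 2 or mutant CD71-positive array 1 (adjusted p = 0.052, 0.11 and 0.055). Markers of myeloid and dendritic cells did not pass this test (median 0.03, adjusted p = 0.31), except without mutant CD71-positive array 2 (adjusted p = 0.026), and Cd74 averaged 5.45 in wild-type and 5.60 in mutant CD71-negative cells.

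**Figure D2:**
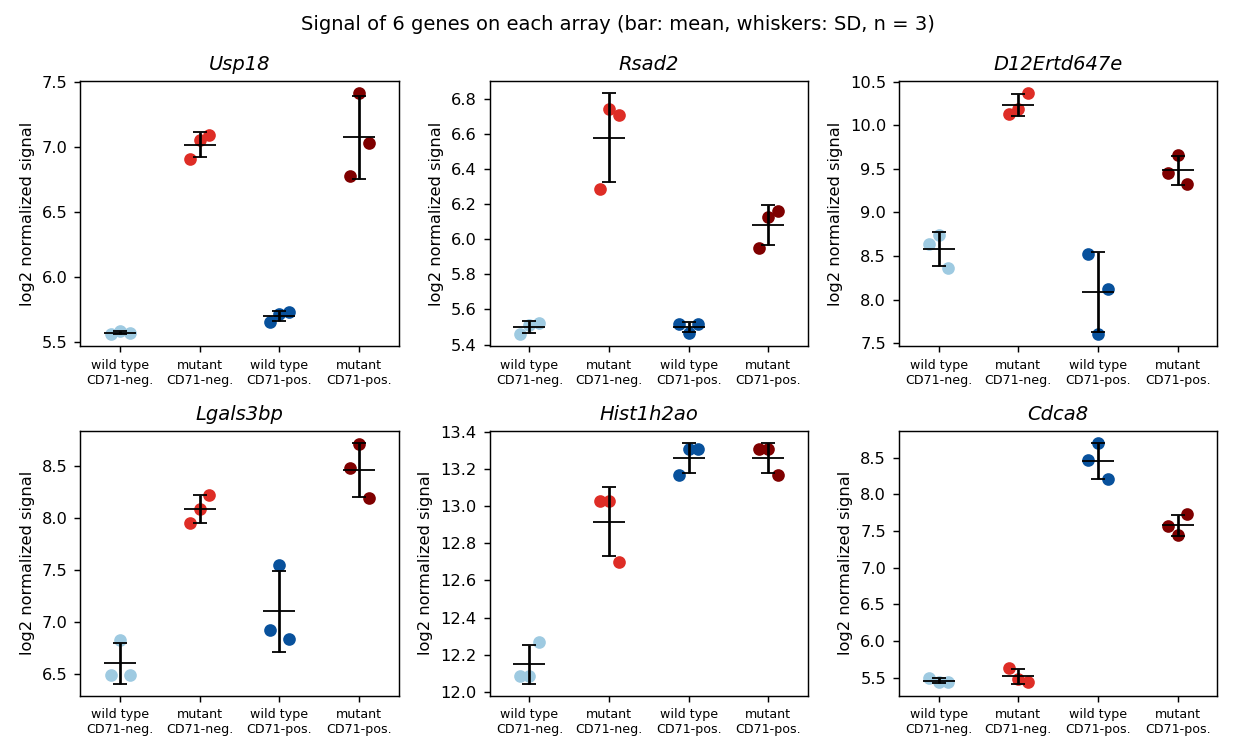
Normalized log2 signal (y axis) of 6 genes on each array of the 4 groups (x axis), with bars for the mean and whiskers for the SD of 3 arrays. Mutant arrays lie above wild-type arrays for Usp18, Rsad2, D12Ertd647e and Lgals3bp in both subsets, and Cdca8 is lower in mutant than in wild-type CD71-positive cells by 0.88 on the log2 scale.

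In CD71-positive cells, D12Ertd647e (Ifi27), Usp18 and Lgals3bp had the largest rises in mutants among genes past the threshold with a matched symbol. LOC100044190, which has no match and was named after its values were seen, was 1.6 higher (adjusted p = 5.5e-05). D12Ertd647e was higher by 1.40 ± 0.21 (adjusted p = 0.034), Usp18 by 1.37 ± 0.13 (2.59-fold, adjusted p = 0.0067), Lgals3bp by 1.36 ± 0.20 and Psmb9, an interferon-inducible immunoproteasome subunit gene, by 0.90 ± 0.15. The nucleotidase gene Entpd4 (0.85 ± 0.09), Uaca, the nucleolar protein gene Nol10, Ehd4, the nuclear pore gene Nup43 and Nudt19 rose by 0.58 to 0.85. E2f1, a transcription factor of the G1/S transition, rose by 0.50 ± 0.05 (adjusted p = 0.0067). The largest falls were those of Ssbp2, a single-stranded DNA binding protein gene (-0.98 ± 0.11, adjusted p = 0.0072), Cdca8, the borealin subunit of the chromosomal passenger complex (-0.88 ± 0.12, adjusted p = 0.022), and Fgf13, which no mutant CD71-positive array detected and which was at least 1.82-fold lower. Pp11r (Endou), Unc84b (Sun2), an inner nuclear membrane protein gene, Prnp, Chchd2, Tbl2, Zfp41 and Mxd3 fell by 0.27 to 0.54. Pp11r, Unc84b and Zfp41 lie within 20 Mb of Ncaph2, and here too nearby genes were listed for the averaged contrast only. In all 35 genes passed, 24 higher and 11 lower. Each was without overlap of the arrays, which selection by p-value favours (10% by chance in unselected genes). Of the 35, 6 of the higher and 1 of the lower were also called in CD71-negative cells, against 0.067 and 0.016 for independent lists. The 2 contrasts share each gene's estimate of spread, so independence understates the overlap to be had by chance. The count was 14, 16, 18, 17, 15, 16, 22 and 61 without wild-type CD71-negative array 1 or 2, wild-type CD71-positive array 3, mutant CD71-negative array 2 or 3, or mutant CD71-positive array 1, 2 or 3 in that order. It was 6 with cyclic loess (3 higher, 3 lower), 17 with no background correction (14 and 3), 16 with normexp (13 and 3), 22 with the authors' values, 16 with no filter, 2 when only these arrays were fitted and 207 with array weights. The split was 26 higher and 3 lower with the background from dim genes.

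By list in CD71-positive cells, replication genes lay mostly above 0 and mitosis genes mostly below, with 1 call each over all genes, and the 2 lists were not tested against each other. Of the 27 replication genes 1 rose and 0 fell (3 and 0 adjusted over the list alone: E2f1, the chromatin assembly gene Chaf1b at 0.61 and Mcm10 at 0.34), and 23 lay above 0, with a median of 0.28 (adjusted p = 7.1e-09, adjusted p = 0.15 with an estimated correlation). Of the 22 mitosis genes 1 fell and 0 rose, both over all genes and over the list alone, and 1 lay above 0, with a median of -0.24 (adjusted p = 1.6e-07, adjusted p = 0.15 with an estimated correlation). The interferon list had 1 gene higher and 0 lower of 17 (7 and 0 adjusted over the list alone), among them Rsad2 at 0.58 and Bst2 at 0.40 (median 0.10, adjusted p = 2.8e-12, adjusted p = 0.054 with an estimated correlation). Ly6a, a surface protein gene on that list which also lies within 20 Mb of Ncaph2, was 2.06 ± 0.36 higher and did not pass over all genes (adjusted p = 0.059). The double-positive thymocyte list was shifted down, with 0 calls over all genes and 3 lower over the list alone, among them the chromatin organizer gene Satb1 at -0.65 and Ets1 at -0.48 (median -0.29, adjusted p = 6.7e-06, adjusted p = 0.054 with an estimated correlation). Genes of Myc and ribosome biogenesis were shifted up with a median of 0.17 (0 calls over all genes, 1 over the list alone, Rrp12 at 0.53, adjusted p = 1.5e-05, adjusted p = 0.066 with an estimated correlation). Ribosomal protein genes (median 0.17, adjusted p = 0.00087) and genes of double-negative thymocytes and Notch signalling (median 0.07, adjusted p = 0.0066) had 0 calls, with adjusted p = 0.24 and 0.23 with an estimated correlation. Histones did not shift here (median 0.01, adjusted p = 0.78), except without wild-type CD71-positive array 1 (adjusted p = 0.0028).

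Markers of antigen-presenting and myeloid cells were measured on the same CD71-positive arrays, and their lists were shifted up by camera with the preset correlation. Testing required detection on at least 3 arrays, so markers detected mainly in mutants are favoured, which may add to the shift. In wild-type CD71-positive cells C1qb averaged 5.43 and C1qc 5.42, near the floor, but Lyz 5.91 and Cst3 7.99. The alternative with no filter kept the same list members and does not check this. The myeloid and dendritic list had 0 of 11 members past the test over all genes and 2 adjusted over the list alone, Lyz (Lyz1) at 1.76 and Lyz2 at 0.29 (median 0.29, adjusted p = 7.1e-09, adjusted p = 0.16 with an estimated correlation). The B cell list, whose 4 tested genes include Cd74, H2-Aa and H2-Ab1, had a median of 0.96 (0 calls over all genes, 1 adjusted over the list alone, adjusted p = 0.018, adjusted p = 0.22 with an estimated correlation). The other tested gene, the B cell receptor component gene Cd79b, differed by -0.03 (adjusted p = 1.0). The list's call was lost without wild-type or mutant CD71-positive array 2 (adjusted p = 0.11 for each). Cd74, the invariant chain of MHC class II, averaged 7.95 ± 1.5 in mutant and 6.62 ± 0.45 in wild-type CD71-positive cells (SD, n = 3), and reached 9.31 on mutant array 2, where Ly6a was also highest at 9.55.

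**Figure D3:**
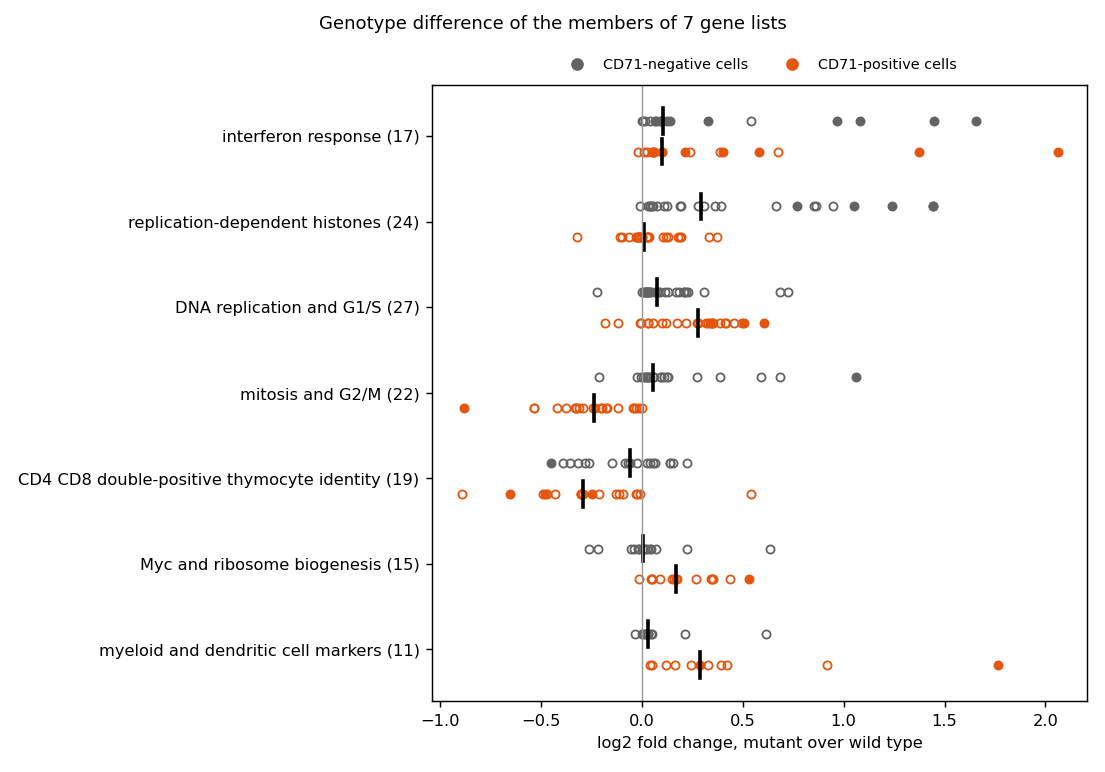
Log2 fold change of mutant over wild type (x axis) for each tested member of 7 gene lists (y axis, number of genes in parentheses), in CD71-negative (grey) and CD71-positive cells (orange). Filled points passed an adjusted p under 0.05 over the list alone and black bars are medians; the mitosis list has a median of 0.06 in CD71-negative and -0.24 in CD71-positive cells.

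Averaging the genotype difference over both subsets sets 6 mutant arrays against 6 wild-type arrays. The labels do not say whether replicate numbers pair the samples, so the arrays of the 2 subsets may not be independent. Among genes with a matched symbol, Usp18 had the smallest p-value, with a rise of 1.41 ± 0.09 (2.66-fold, adjusted p = 0.00032), followed by Entpd4 at 0.83 ± 0.06 (adjusted p = 0.00047). D12Ertd647e (Ifi27) rose by 1.53 ± 0.15, Lgals3bp by 1.42 ± 0.14, the MHC class I-like gene H2-T10 by 1.36 ± 0.23 and Prr13, which lies within 20 Mb of Ncaph2, by 1.26 ± 0.17. The ribosomal protein gene Rps27l, Psmb9, Rsad2 and A230050P20Rik (Shfl) rose by 0.82 to 0.86. Fgf13, which no mutant CD71-positive array detected, the focal adhesion gene Zyx (-0.61 ± 0.11), P2ry5 (Lpar6), Sav1, Prnp (-0.50 ± 0.05, adjusted p = 0.0022) and the lymphoid transcription factor gene Ets1 (-0.47 ± 0.07, adjusted p = 0.031) fell, as did Ccdc92, Zdhhc14, Unc84b (Sun2) and Zcchc6 (Tut7). Satb1 at -0.52 and Runx1 at -0.33 also passed. In all 75 genes passed, 49 higher and 26 lower. For 59 of them the arrays did not overlap in either subset and differed the same way in both, which selection by p-value favours. By chance 10% of unselected genes do not overlap within 1 subset. The count was 28, 31, 127, 38, 33, 39, 27 and 36 without wild-type CD71-negative array 1 or 2, wild-type CD71-positive array 1, 2 or 3, mutant CD71-negative array 2, or mutant CD71-positive array 1 or 2 in that order. It was 18 with cyclic loess, 117 with normexp, 35 with no filter and 554 with array weights. The split was 46 higher and 48 lower without wild-type CD71-negative array 3, 278 and 276 with array weights, and 50 and 11 with the trended robust fit.

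The interferon list had 6 of 17 members higher and 0 lower in the average, and 14 and 0 adjusted over the list alone (median 0.10, adjusted p = 6.1e-16). It was the 1 list of the genotype comparisons whose call held with an estimated correlation (adjusted p = 0.037). With the preset correlation it kept its call when each array was left out, with a camera adjusted p of at most 7.4e-12. The estimated correlation was not run with arrays left out. The difference of Cd74 was 0.15 in CD71-negative and 1.33 ± 0.60 in CD71-positive cells and passed in neither (adjusted p = 0.98 and 0.61). A further 11 lists passed with the preset correlation alone. By median they were B cell markers (0.54), ribosomal proteins (0.27), histones (0.20), replication genes (0.20, 1 of 27 higher, 4 adjusted over the list alone), leukaemia genes (-0.17) and myeloid markers (0.15), with adjusted p = 0.22, 0.21, 0.21, 0.18, 0.12 and 0.21 with an estimated correlation. Smaller medians were those of innate-like T cell markers (0.14), Myc genes (0.06), double-negative thymocyte genes (0.06) and p53 targets (0.02), with adjusted p = 0.21, 0.18, 0.21 and 0.12 with an estimated correlation. The B cell call was kept without 5 of 12 arrays and lost without wild-type CD71-negative array 1 or 3, wild-type CD71-positive array 2, mutant CD71-negative array 1, 2 or 3, or mutant CD71-positive array 2 (adjusted p up to 0.117). The p53 call was kept without 9 of 12 and lost without wild-type CD71-negative array 2, wild-type CD71-positive array 1 or mutant CD71-positive array 3 (adjusted p up to 0.082). The double-positive list had 2 members lower, Ets1 and Satb1, and 0 higher of 19 (adjusted p = 0.0016, adjusted p = 0.12 with an estimated correlation). Condensin subunits (adjusted p = 0.88), DNA repair (0.57), iron handling (0.90), glycolysis (0.24), cholesterol synthesis (0.90), apoptosis regulators (0.79), immediate-early genes (0.88), thymic stroma markers (0.21) and sex-linked genes (0.84) passed in no genotype comparison as lists on all 12 arrays with the main settings. In CD71-negative cells glycolysis passed without wild-type CD71-negative array 3, wild-type CD71-positive array 1 or 2 or mutant CD71-negative array 1 (adjusted p = 0.0044, 0.040, 0.029 and 0.040). Stroma markers passed there without wild-type CD71-negative array 1 or mutant CD71-negative array 3 (0.011 for each), immediate-early genes without the latter (0.011) and sex-linked genes without mutant CD71-negative array 1 (0.042). DNA repair passed in CD71-positive cells without mutant CD71-positive array 2 (0.014), and immediate-early genes without mutant CD71-positive array 1 (0.050). For the interaction, the lowest such values were 0.0063 for immediate-early genes, 0.0097 for glycolysis, 0.032 for stroma markers and 0.036 for DNA repair, and for the average 0.040 for glycolysis. The iron exporter gene Slc40a1, which no wild-type CD71-negative array detected, rose in the average.

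**Figure D4:**
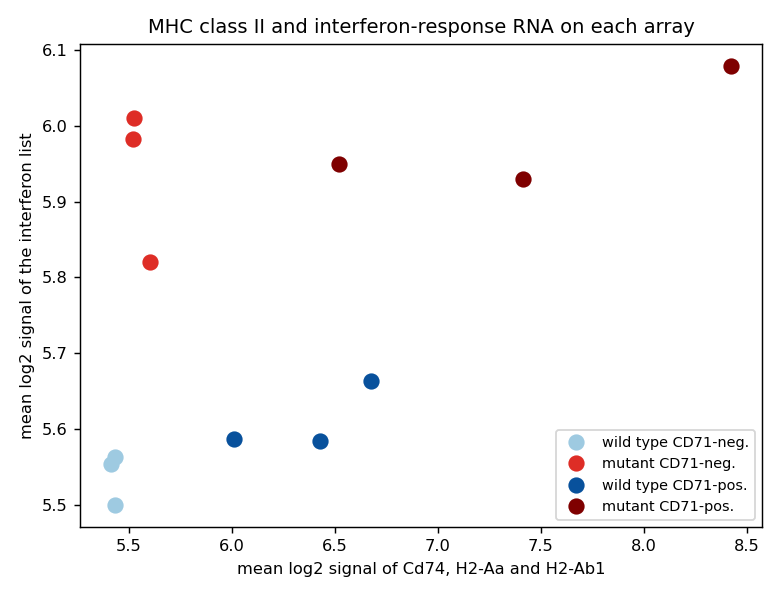
Mean log2 signal of the 17 tested interferon-response genes (y axis) against that of Cd74, H2-Aa and H2-Ab1 (x axis), 1 point per array, coloured by group. Mutant CD71-negative arrays have more interferon-response RNA than wild-type CD71-positive arrays, by 0.33, and less class II RNA, by -0.82. Within CD71-negative cells mutant arrays have more of both, by 0.40 and 0.12.

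Whether the genotype difference itself differed between subsets was tested by the interaction, CD71-positive minus CD71-negative. The 1 gene past the threshold, LOC100044190, was named because the count was so small and was chosen after its values were seen. It has no match to a current symbol. LOC100044190 was 0.51 higher in mutant than in wild-type CD71-negative cells and 1.6 higher in CD71-positive cells. The difference was 1.09 ± 0.11 (adjusted p = 0.033). At an unadjusted p under 0.05 there were 466 genes. Next by p-value, none of them past the threshold (adjusted p = 0.24), were Nol10, Samsn1, Dpp3 and Zmym3, between 0.31 and 0.80, Shmt2, which no mutant CD71-negative array detected, and Ssbp2, 4933439C20Rik (Pisd-ps3), Hist1h2ao (H2ac23), Epsti1 and Chchd2, between -1.0 and -0.50. The count was 0 without wild-type CD71-negative array 1 or 2, wild-type CD71-positive array 1, mutant CD71-negative array 2 or 3, or mutant CD71-positive array 1 or 3, was 5 without wild-type CD71-negative array 3 and was 3 without wild-type CD71-positive array 2. Without mutant CD71-positive array 2 it was 1, a gene other than LOC100044190.

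Among lists, mitosis genes had the smallest p-value for the interaction, with 0 of 22 members called over all genes and 5 lower adjusted over the list alone, Cenpa at -1.26, Top2a at -1.22, Prc1 at -1.12, Cdca8 at -0.94 and Plk1 at -0.31 (median -0.33, adjusted p = 3.0e-09, adjusted p = 0.32 with an estimated correlation). Histones were also lower in the interaction (median -0.18, 0 calls over all genes and 2 lower adjusted over the list alone, adjusted p = 1.2e-06, adjusted p = 0.33 with an estimated correlation). Myeloid markers (median 0.19, adjusted p = 0.00051), Myc genes (0.20, adjusted p = 0.0049) and the double-positive list (-0.19, adjusted p = 0.016) also passed with 0 calls, at adjusted p = 0.59, 0.33 and 0.33 with an estimated correlation. The double-positive call was lost without wild-type CD71-negative array 2 or wild-type CD71-positive array 3 (adjusted p = 0.084 and 0.14). The interferon list did not differ between subsets by this test (median -0.02, adjusted p = 0.29), except without mutant CD71-negative array 1 (adjusted p = 0.030). Across the 8247 genes, which are not independent replicates, the genotype differences of the 2 subsets correlated at r = 0.35 ± 0.23 (Pearson, SE from leaving out each array) and rho = 0.27 (Spearman). The value of r fell between 0.16 and 0.45 when 1 array was left out.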

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

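The tests of array brightness, of RNA from antigen-presenting cells and of the share of cycling cells were chosen only after the results were seen, while the other divisions of the arrays and the position test near Ncaph2 were planned.

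The interferon list was shifted up in mutants in both subsets, with 3 and 1 of 17 genes past the test over all genes, and both calls were lost with an estimated correlation (adjusted p = 0.080 and 0.054). With array brightness as a covariate the list kept an adjusted p of 1.7e-13 in the averaged contrast, by camera with the preset correlation. Its median was 0.10 without and 0.097 with the covariate, so a linear adjustment for brightness did not remove the shift. The estimated correlation was not run with the covariate, so brightness is not excluded. In CD71-negative cells MHC class II RNA (Cd74, H2-Aa, H2-Ab1), abundant in antigen-presenting cells, was near the floor but higher on each mutant array (5.52 to 5.60) than on each wild-type array (5.42 to 5.43), by 0.12 on average against 0.40 for the interferon list. Mutant CD71-negative arrays had less class II RNA than wild-type CD71-positive arrays, by -0.82, and more of the interferon list, by 0.33, but a comparison between subsets does not settle a difference within one. In CD71-positive cells the 8 markers of other cell types that no wild-type CD71-negative array detected had a median difference of 0.27. Testing required detection on at least 3 arrays, so these markers were partly selected for being higher in other groups, mutants included. Their positive median is therefore no separate evidence. Sorting on both CD4 and CD8 should remove most antigen-presenting and myeloid cells. Even so, RNA of such cells and a response of the thymocytes to the genotype cannot be told apart in either subset.

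Histone genes were shifted up in mutant CD71-negative cells, with a lower genotype difference in CD71-positive cells (adjusted p = 1.2e-06 for the difference), and both calls were lost with an estimated correlation (adjusted p = 0.21 and 0.33). Brightness as a covariate left the list in CD71-negative cells at a camera adjusted p of 5.8e-08 with the preset correlation. Its median was 0.29 without and 0.25 with the covariate, so a linear adjustment for brightness did not remove the shift. The estimated correlation was not run with the covariate, so brightness is not excluded. The share of wild-type CD71-positive signal needed was 20.6% for 10 histone genes (10.4% to 44.3% per mutant array), 2.49% for replication genes (0.91% to 5.11%) and 0.94% for mitosis genes (0.35% to 1.74%), each above every wild-type array for its list. Only members with wild-type CD71-positive signal well above the wild-type CD71-negative mean were used. That mean was also the baseline, so genes low by chance in wild type are favoured and the shares may be too high. Wild-type arrays centre on the baseline by construction. More cycling cells in the gate, or more of them in S phase, cannot be told apart from a change in histone RNA, since the profile of such cells in mutants is not known. Near-identical copies, and the lack of a poly(A) tail on most of these messages, stay open as technical explanations, untested, beside an effect of the genotype.

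Genes called in the averaged genotype contrast lay near Ncaph2 somewhat more often than others, with 5 of 70 within 20 Mb against 229 of 7784 (odds ratio 2.54, confidence interval 0.79 to 6.32, Fisher's exact test, two-sided p = 0.057). The 5 genes were Kcnh3, Pp11r (Endou) and Unc84b (Sun2), which fell, and Prr13 and Phf5a, which rose. Nearby genes called in a single subset but not in the average were not counted. Variants carried along with the induced mutation could change the level or the probe binding of such genes, and the test is too small to settle it. The odds ratio was 4.0 within 10 Mb, 2.67 for the 100 smallest p-values and 1.84 for the whole chromosome (Fisher's exact p = 0.022, 0.022 and 0.21). Such variants and an effect of the Ncaph2 change itself on these genes cannot be told apart in a design with 1 mutant line.

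Other differences between the subsets' genotype effects stood out by a test of the difference itself. The mitosis list differed at an adjusted p of 3.0e-09, the myeloid and dendritic list at 0.00051, the Myc and ribosome biogenesis list at 0.0049 and the double-positive thymocyte list at 0.016, and none of them held with an estimated correlation. LOC100044190 differed by 1.09.

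Other divisions of the same arrays were fitted in the same way. The average called 75 genes, and 2 of 100 divisions, the real one included, called as many. That share lies under 0.05, so such a count is uncommon among the divisions, but it does not exclude chance. The other of these 2 divisions called 865 genes, several times the real count, which points to a structure of the samples. It has the largest gap in brightness of the 100, but the divisions ranked 2, 3 and 4 by that gap called 0 genes each, so brightness is not shown to be that structure. With brightness as a covariate the average called 67 genes, 52 of them shared with the 75. For the interaction 26 of 100 divisions called at least the 1 gene of the real division, up to 82. Divisions that exchange genotypes in 1 subset, wholly or in part, carry the averaged genotype difference into the interaction. This share therefore does not measure chance for the interaction, and chance is not excluded. With 10 divisions of 6 arrays the share cannot fall under 0.05. The real and highest other counts were 35 and 35 in CD71-negative cells (2 of 10 as large), 35 and 6 in CD71-positive cells (1 of 10), 2067 and 4 between wild-type subsets (1 of 10) and 2375 and 0 between mutant subsets (1 of 10). In CD71-negative cells the other division with 35 genes set wild-type arrays 1 and 2 and mutant array 1 apart, again the largest gap in brightness, while those ranked 2, 3 and 4 called 0. In CD71-positive cells the division with the largest gap called 0. With brightness as a covariate the real division called 29 in CD71-negative cells.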

How the results depend on the processing

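The brightness covariate and the background from dim genes were chosen after the data were seen, and all other alternatives were planned. No result changed direction past its threshold. Genes named among those past it kept their call in 5109 tests under alternatives and lost it in 754. Lists kept it in 1265 and lost it in 148. Named genes and lists not called in the main fit gained a call in 272 and 117 tests. These totals pool all contrasts, including those between subsets. There 68 of 82 named genes in wild type and 75 of 93 in mutants kept their call in every alternative. The totals therefore do not describe the genotype calls. In the averaged contrast 6 of 27 named genes kept their call in every alternative (D12Ertd647e, Entpd4, Lgals3bp, Prnp, Prr13 and Usp18), and 11 when each array was left out. In CD71-negative and CD71-positive cells 0 of 22 did so in every alternative and 6 of 22 when each array was left out, Usp18 among them in both. The fit of only the arrays compared was not run for the average and left 2 calls in each subset. The numbers kept in every alternative are therefore not alike between the average and the subsets. For genes close to background, the offset and the background estimate set the size of a change, which limits what these arrays can show of them.

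Counts of genes past the threshold that moved by over 1.5 times are given for CD71-negative cells (35), CD71-positive cells (35), the average (75) and the interaction (1). Cyclic loess gave 8, 6, 18 and 0, and no filter 20, 16, 35 and 0. Array weights gave 461, 207, 554 and 45, and 4358 between mutant subsets. Normexp gave 16 in CD71-positive cells, 117 in the average and 0 in the interaction, and no background correction 17 in CD71-positive cells. The authors' values gave 55, 22 and, in the interaction, 0. The trended robust fit gave 53 in CD71-negative cells and the background from dim genes 59, both with 0 in the interaction. Fitting only the arrays compared gave 2 in each subset, where fewer arrays estimate the spread. Brightness as a covariate gave 0 in the interaction. The cause of these changes was not tested.

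The labels do not say whether replicate numbers pair the samples. They were not taken to, since the deviations of same-numbered arrays correlated at -0.41 to 0.59, over 0.1 in 11 of 18 pairs but not in all. Only the 2 subsets of a genotype could come from the same animal. Their same-numbered arrays correlated at -0.41, 0.39 and 0.26 in wild type and 0.51, -0.30 and 0.50 in mutants. Such pairing is neither shown nor excluded. If it holds, the averaged contrast and the correlation of genotype effects treat paired arrays as independent. As a hint from the data, 7 of 12 arrays correlated best with an array of their own number in another group, of either genotype. This count was not set against chance. The replicate block joins same-numbered arrays of both genotypes, so it does not model pairing of subsets within an animal. It gave 23 genes in CD71-positive cells and 0 in the interaction.

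Of lists called, the estimated correlation gave 0, 0, 1 and 0 in these contrasts, 3 between wild-type subsets and 4 between mutant subsets. Fry gave 4 in CD71-negative cells, 4 in the average, 0 in the interaction and 19 between mutant subsets, and no filter gave 17 between mutant subsets. The odds ratio near Ncaph2 passed within 10 Mb (4.0) and for the 100 smallest p-values (2.67).

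Leaving out 1 array at a time gave 14 to 123 genes in CD71-negative cells, 14 to 61 in CD71-positive cells, 27 to 127 in the average, 0 to 5 in the interaction, 1529 to 2157 between wild-type subsets and 1782 to 2511 between mutant subsets. Lists called ranged from 4 to 11, 8 to 10, 11 to 13, 4 to 7, 8 to 10 and 9 to 13 in that order, with the 4 in CD71-negative cells without wild-type CD71-negative array 3. Ncaph2 ranged from -0.27 to -0.03 and from -0.14 to 0.09 between genotypes in the 2 subsets, from 1.06 to 1.31 between wild-type subsets and from 1.20 to 1.38 between mutant subsets. The correlation of genotype effects ranged from 0.16 to 0.45.

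The slide as a block was not run, since the files used here give no slide, and the mean of a gene's probes was not run, since the table has 1 entry per gene.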

Other observations

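No test was added for this part after the results were seen, and its values come from the planned contrasts and lists.

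Several targets of p53 were lower in CD71-positive than in CD71-negative cells, although the list as a whole did not pass by camera (adjusted p = 0.19 in wild type and 0.054 in mutants). In wild type 4 of 21 members fell and 1 rose, and in mutants 7 fell and 1 rose, with the same counts adjusted over the list alone. Over all 8247 genes tested, 1080 fell and 987 rose in wild type, and 1182 fell and 1193 rose in mutants. Changed members are therefore common in any list. Trp53inp1, which promotes apoptosis and autophagy, was lower by -1.77 in wild type and -1.81 in mutants, the death receptor gene Fas by -1.30 and -1.74, and the stress-response gene Sesn1 by -0.98 and -1.17. Lrdd (Pidd1), which no wild-type CD71-negative array detected, was the member that rose, at least 1.14-fold in wild type. Mdm2 passed in mutants at -0.49, and Bbc3 at -1.0 and Gadd45a at -1.15 did too.

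Iron handling genes moved both ways between subsets. Besides Tfrc, whose rise follows the sort, the mitochondrial iron importer gene Slc25a37 was lower in CD71-positive cells by -1.55 in wild type and -1.41 in mutants, and the ferritin gene Fth1 by -0.30 and -0.47. The iron exporter gene Slc40a1 was higher in mutant than in wild-type CD71-positive cells by 0.34 and passed over all genes. No wild-type CD71-negative array detected it, and markers of myeloid cells were shifted up on the same CD71-positive arrays. Which cells its RNA came from was not tested. Of the 8 tested genes 1 rose and 3 fell in wild type, and 2 rose and 2 fell in mutants. The list did not pass by camera (adjusted p = 0.34 and 0.56).

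LOC100044190, named after its values were seen, had the largest mutant excess relative to its spread in CD71-positive cells (1.6, adjusted p = 5.5e-05). Its 3 mutant CD71-positive arrays lay between 7.91 and 7.96 and its 3 wild-type CD71-positive arrays between 6.21 and 6.45.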
